A study of Mus musculus with 18 samples.

How the data were processed

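The deposited values are FPKM per gene for 18 libraries and 37319 genes, with 1 column per library whose name matches the title of the sample. Per the submitters' processing notes, reads were mapped with HISAT, assembled and quantified as FPKM with StringTie, and tested with edgeR, with no versions stated and genome build mm9. Per the labels' protocols, libraries were poly(A) selected and stranded, with paired-end reads. Read counts were not used here, so the tests rest on FPKM and the deposited unit gives no read totals, so that only a rough relative depth could be had.

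The comparisons, gene lists, tests and thresholds were written down before the data were examined. log2(FPKM + 1) was tested with limma 3.58.1 (trend, empirical Bayes) in R 4.3.3, two-sided, with the libraries of the groups compared only. Genes needed at least 1 FPKM in at least 3 libraries of the fit, and p was adjusted over these genes by Benjamini and Hochberg at 0.05. A gene near 0 in sham was thus tested only if high in the other group. This can raise the share of tested list members that rose. The pseudocount of 1 makes log2 differences of low genes smaller than their ratios. Figures and assembly used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Single values were compared by exact two-sided permutation tests. Labels do not say that the libraries are separate mice, so p-values measure the spread between these libraries.

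The 36 gene lists held markers and pathway genes from general knowledge, and lists with at least 4 measured members were tested with camera (preset correlation of 0.01, and an estimated correlation) and with fry, adjusted over the lists. Calls of list members are given over all genes and adjusted over the list alone. Genes named in the text were drawn by a rule written before the data were examined: the 10 largest changes each way among genes that passed without overlap of the groups, up to 4 passing members of a list or else the 2 with the smallest p, every member of the aryl hydrocarbon receptor and PARP lists, and, where fewer than 10 passed in a direction, these and the next 5 by p. Tiparp is always given. The text names a part of these genes, picked after their values were seen, and the rest are in the counts. There were 62 repeated symbols, and of several entries the one with the highest mean was used.

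The same code was tested on simulated data with 200 changed genes for each comparison. It recovered 78% of changes of 1 and 95% of changes of 2 on the log2 scale for the control arm at 24 h, with 4.95% false calls. For the Tiparp arm at 24 h these were 59%, 79% and 4.17%, for the sham arms 90%, 93% and 4.19%, and for the arms at 24 h 42%, 89% and 2.96%. For the arms at 28 d they were 69%, 96% and 4.07%, for the 24 h interaction 48%, 79% and 4.51%, and for the 28 d interaction 67%, 93% and 6.43%. For 28 d against 24 h in the control arm they were 75%, 92% and 7.73%, the highest share of false calls. Against sham at 28 d they were 84%, 92% and 4.86% in the control arm and 74%, 94% and 5.62% in the Tiparp arm. Over all 3 conditions they were 93%, 95% and 3.59%. The simulated noise was independent between genes, with the same SD in the groups compared. In the real data genes varied together. The median SD on the log2 scale was 0.19 in the control arm at 24 h and 0.0871 in control-arm sham. These rates therefore need not hold for the real libraries. Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, the replicate number as a block, array weights, all 18 libraries in 1 fit and each library left out. A gene annotation of another build was used only to find which gene models overlap, and it matched 37225 of the gene IDs (99.7%).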

Results

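RNA-seq was done on the ipsilateral cortex of male C57BL/6J mice aged 8 to 10 weeks and weighing 24 to 26 g. An adeno-associated virus (AAV) with a synapsin promoter, which is active in neurons, carried a short hairpin RNA (shRNA) into the left lateral ventricle. The shRNA was directed against Tiparp (the Tiparp arm) or was a scramble control (the control arm). Surgery followed 4 weeks later and was either sham or transient middle cerebral artery occlusion (tMCAO), in which the artery that feeds lateral cortex and striatum is blocked and reopened. Cortex was taken 24 h or 28 d after tMCAO. The 18 libraries formed 6 groups of 3, named Sham_C, Sham_T, R24h_C, R24h_T, R28d_C and R28d_T for condition and arm (C, control; T, Tiparp). The deposited values were FPKM, which hold no read totals. The lowest values of the same genes gave a rough depth of the libraries between 0.934 and 1.08 times that of Sham_C1, from a ratio at which 3.74% to 4.75% of the low genes lay. Pearson's r between libraries of a group, across genes, was 0.983 to 0.984 in Sham_C and 0.980 to 0.984 in Sham_T, and 0.944 to 0.965 in R24h_C and 0.947 to 0.955 in R24h_T. It was 0.972 to 0.980 in R28d_C and 0.944 to 0.968 in R28d_T.

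Tiparp (ENSMUSG00000034640), also called PARP7, encodes a mono-ADP-ribosyltransferase that the aryl hydrocarbon receptor induces. In sham cortex it was at 4.17, 4.95 and 4.57 FPKM in Sham_T1, Sham_T2 and Sham_T3, and at 4.45, 4.76 and 3.77 FPKM in Sham_C1, Sham_C2 and Sham_C3. At 24 h it was at 3.99, 5.0 and 3.01 FPKM in R24h_T1, R24h_T2 and R24h_T3, against 6.66, 4.60 and 8.65 FPKM in R24h_C1, R24h_C2 and R24h_C3. At 28 d it was at 3.97, 4.06 and 3.72 FPKM in the R28d_T libraries and at 4.46, 3.59 and 3.78 FPKM in the R28d_C libraries. The Tiparp arm minus the control arm was 0.06 in sham, -0.60 at 24 h (60.2% of the control mean of 6.64 ± 2.02 FPKM, SD, n = 3) and 0.00 at 28 d, on the log2(FPKM + 1) scale. Exact two-sided permutation tests gave p = 0.6 in sham, p = 0.2 at 24 h and p = 1 at 28 d, where 3 libraries against 3 cannot go below 0.1. A permutation test of the arms within each condition gave a difference of -0.18 with p = 0.196 over 8000 labellings. That difference was -0.10 without R24h_C3, -0.11 without R24h_T3 and -0.02 with array weights. Leaving out Sham_C3 turned the sham difference to -0.01. No difference in Tiparp between the arms passed at any of the 3 times. Whole cortex also holds RNA of cells in which a synapsin promoter is not active. In the control arm Tiparp was 0.49 higher at 24 h than in sham and did not pass (limma adjusted p = 0.117).

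**Figure D1:**
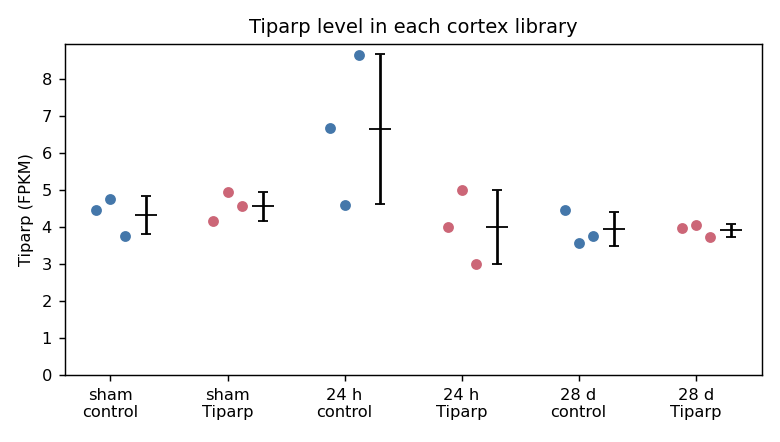
Tiparp in FPKM (vertical axis) in each of the 18 libraries, by group (horizontal axis). Blue points are control-arm and red points Tiparp-arm libraries, and the black bars are mean ± SD of 3 libraries, such as 6.64 ± 2.02 in R24h_C and 4.0 ± 0.997 in R24h_T.

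The sham groups compare the arms without ischemia. Tiparp was at 105% of the control mean in Sham_T, so the differences below are between the groups and are not tied to a knockdown. Plin4, Sult1a1 and Fkbp5 are also on a glucocorticoid-responsive list, written after their values were seen. That list was lower in Sham_T in 21 of 21 members, as described further below. Plin4, a lipid droplet coat protein, fell from 10.2 ± 2.0 FPKM in Sham_C to 1.09 ± 0.530 FPKM in Sham_T (SD, n = 3 per group; log2 difference -2.44, SE 0.20, limma adjusted p = 0.0119). The astrocyte phospholyase gene Etnppl fell from 10.2 ± 1.26 to 3.61 ± 0.537 FPKM (log2 difference -1.29, adjusted p = 0.016). The phenol sulfotransferase Sult1a1 (-1.18) and Fkbp5 (-1.01), a chaperone of steroid receptors, fell with adjusted p = 0.00089 and 0.00561. Rnf144a, a ubiquitin ligase, Rtp1, Gabrr2, Alox12b and Pla2g3 also fell, with log2 differences of -1.10, -1.25, -0.86, -0.80 and -0.78.

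Among marker lists, 1 of 13 astrocyte markers fell, the gap junction gene Gjb6 (-0.65, adjusted p = 0.0478); adjusted over the list alone, 2 were higher and 3 lower. Of 8 endothelial markers the lipid transporter Mfsd2a fell (-0.99, adjusted p = 0.0332), and 2 were lower adjusted over the list alone. The transferrin gene Trf rose from 17.0 ± 1.35 to 32.2 ± 3.05 FPKM (log2 difference 0.89, adjusted p = 0.0188). Fcrls (0.82), expressed in microglia, Lyz2 (0.66), a lysozyme of myeloid cells, Ecel1 (0.88), Ctdsp2 (0.93) and Tmem88b (0.71) rose as well. Of 13 oligodendrocyte and myelin genes none passed over all genes and 5 were higher adjusted over the list alone, with the myelin proteins Cnp and Mag at log2 differences of 0.49 and 0.58 (adjusted p = 0.145 and 0.176). Of 5 choroid plexus and ependymal markers 2 were higher adjusted over the list alone. The choroid plexus product Ttr was at 624 and 501 FPKM in Sham_T1 and Sham_T2 and at 7.39 FPKM in Sham_T3, against 9.87 to 13.4 FPKM in Sham_C. Sham_T3 stood apart in the blood cell and meningeal list (-1.5 from the Sham_C mean, against 0.13 and 0.37 in Sham_T1 and Sham_T2; median of the arms -0.43) and in the striatal list (1.05, against -0.13 and 0.12; median 0.34). Of 14 PARP family and 6 aryl hydrocarbon receptor pathway genes none passed, with medians of 0.02 and -0.02.

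The genes with the highest rises, Chd3os (1.55), the glucose transporter Slc2a3 (1.25), the F-box protein gene Fbxo41 (1.2) and Fam109a (1.11), each had a high and a low cluster of values over the 18 libraries. In each of them some groups outside this comparison held libraries of both clusters. Slc2a3 was at 5.02 to 6.05 FPKM in 6 libraries and at 12.8 to 19.5 FPKM in 12.

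limma called 11 genes higher and 17 lower of 13349 tested between the sham arms. The values of 19.5% of the genes did not overlap between the groups, where chance gives 10%. Camera with a preset correlation of 0.01 called 8 of 32 lists and none with an estimated correlation (lowest adjusted p = 0.48 with an estimated correlation). Without Sham_C1, Sham_C2 or Sham_T1 the count of genes fell to 17, 5 or 12, and without Sham_T3 it was 52. It was 0 with all 18 libraries in 1 fit, 6 with no filter and 6 with the replicate block. Without Sham_T1 and Sham_T2, the libraries with high Ttr, which leaves 1 Sham_T library, 4 genes were higher and 17 lower, and 4 of the 28 were kept. Of the 21 passing genes named here 4 passed without each library in turn.

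Control-arm cortex 24 h after tMCAO, compared with sham, shows the early response to ischemia. Spp1, which encodes the matrix protein osteopontin, rose from 6.55 ± 0.214 to 528 ± 271 FPKM (SD, n = 3 per group; log2 difference 5.95, SE 0.43, limma adjusted p = 0.00151). The acute-phase protease inhibitor Serpina3n rose from 7.67 ± 1.30 to 412 ± 86.4 FPKM (5.57, SE 0.18, adjusted p = 6.89e-05). The lipocalin Lcn2 (5.47), the metalloproteinase inhibitor Timp1 (5.17), the small heat shock protein Hspb1 (4.53) and the transglutaminase Tgm1 (4.59), all on the reactive astrocyte list, rose by more than 4 on the log2 scale. Of 26 reactive astrocyte genes 26 rose, 26 adjusted over the list alone (median 2.34; adjusted p = 0.403 with an estimated correlation).

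Inflammatory genes rose across several lists. Members near 0 in sham were tested only if they reached 1 FPKM in all 3 R24h_C libraries. Shares such as 15 of 15 thus partly follow from this filter. Of 15 cytokines and chemokines 15 rose, 15 adjusted over the list alone, among them the chemokines Ccl2 (4.42), Cxcl1 (4.09) and Ccl3 (3.63) and the interleukin Il11 (3.73). Monocyte and macrophage markers rose in 10 of 10, 10 adjusted over the list alone, with the endotoxin co-receptor Cd14 from 1.0 ± 0.0798 to 52.9 ± 33.6 FPKM (4.44, adjusted p = 0.00692) and the scavenger receptor Msr1 at 3.20. Interferon response genes rose in 16 of 16, 16 adjusted over the list alone, such as the guanylate-binding proteins Gbp2 (3.4, adjusted p = 6.89e-05) and Gbp3 (2.14). The complement inhibitor Serping1 (2.58) and the anaphylatoxin receptor C5ar1 (2.95) were among 11 of 13 complement genes that rose, 12 adjusted over the list alone. MHC and antigen presentation genes rose in 8 of 8, 8 adjusted over the list alone. Neutrophil markers rose in 3 of 4, 3 adjusted over the list alone, with the calprotectin subunits S100a8 and S100a9 at 3.38 and 4.35. Disease-associated microglia genes rose in 14 of 18 (14 rose and 1 fell adjusted over the list alone), with the galectin Lgals3 at 3.93. Homeostatic microglia markers split, and 3 of 12 rose, such as Fcrls (1.93), while 4 fell, such as the purinergic receptor P2ry12 (-1.35) and Gpr34 (-0.91), with the same counts adjusted over the list alone.

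Heat shock genes rose in 12 of 14 (14 adjusted over the list alone), with the collagen chaperone Serpinh1 at 2.12. NRF2 and metallothionein genes rose in 9 of 11 (9 adjusted over the list alone), with heme oxygenase Hmox1 at 4.62 and the metallothionein Mt2 from 91.6 ± 8.70 to 574 ± 143 FPKM (2.61, adjusted p = 0.00145). Unfolded protein and integrated stress response genes rose in 10 of 14 (13 adjusted over the list alone), p53 and apoptosis genes, such as the cell cycle inhibitor Cdkn1a (2.33), in 8 of 13 (13 adjusted over the list alone), and hypoxia genes in 6 of 12 (6 adjusted over the list alone). Endothelial markers rose in 9 of 11 (9 rose and 1 fell adjusted over the list alone), with vascular cadherin Cdh5 at 2.41, mural cell markers in 6 of 9 (7 adjusted over the list alone). Extracellular matrix and scar genes, such as tenascin Tnc (2.91) and the stromelysin Mmp3 (3.62), rose in 13 of 17 and fell in 1 (14 and 1 adjusted over the list alone). Cytosolic ribosomal protein genes rose in 12 of 25 (23 adjusted over the list alone), but in 2 after median-ratio scaling of the libraries. In the aryl hydrocarbon receptor pathway 3 of 8 genes rose, the cytochrome Cyp1b1 (2.21), the galectin-binding protein Lgals3bp (1.96) and the quinone reductase Nqo1 (1.16); adjusted over the list alone 4 rose and 1 fell. In the PARP family 5 of 16 rose (5 adjusted over the list alone, 3 after scaling), including Parp3 (2.40), Parp9 (1.08), Parp12 (0.82) and Parp4 (0.56).

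Synpo, which encodes the actin-associated spine protein synaptopodin, fell from 27.9 ± 3.95 to 5.25 ± 0.560 FPKM (-2.21, SE 0.13, adjusted p = 0.000815). Of 21 immediate early genes 9 fell and 4 rose (10 and 4 adjusted over the list alone). The activity-induced factors Nr4a1 (-1.94), Nr4a2 (-2.06), Egr3 (-1.83) and Egr4 (-2.09) and the dendritic protein Arc (-2.0) fell, while the stress-induced factors Atf3 (3.17) and Fosl1 (2.38) rose. Synaptic genes fell in 7 of 24 (7 adjusted over the list alone), among them the postsynaptic scaffolds Shank1 (-1.04), Shank3 (-0.87) and Dlg4 (-0.73). The synaptic and immediate early lists were not called by fry (adjusted p = 0.0915 and 0.18). Pan-neuronal markers fell in 4 of 14, and 4 fell adjusted over the list alone. The kinase gene Camk2a was the 1 of 13 excitatory neuron markers that fell (-1.05), and 0 passed adjusted over the list alone and 3 after scaling. Of 13 mitochondrially encoded genes 2 fell (4 adjusted over the list alone, 8 after scaling). The share of all FPKM on every gene with a symbol starting with mt- was 35.1% ± 0.929 in R24h_C and 40.0% ± 1.60 in Sham_C (SD, n = 3). None of 12 striatal neuron markers passed, also adjusted over the list alone, and 2 of 4 choroid plexus and ependymal markers rose (3 adjusted over the list alone). R24h_C3 held Ttr at 1682 FPKM, against 7.11 and 13.3 FPKM in R24h_C1 and R24h_C2, and its synaptic list median was -0.82 from the sham mean, against -0.37 and -0.04. Its striatal list median was 1.05, against -1.32 and -0.683 in R24h_C1 and R24h_C2. The striatal markers thus went both ways between these libraries, and the lack of a call does not show that they were unchanged. Over all genes and adjusted over the list alone, the remaining lists had 3 and 3 higher of 12 oligodendrocyte and myelin genes, 1 and 0 higher of 14 inhibitory neuron markers, 4 and 4 higher (and 1 and 1 lower) of 11 growth-associated genes, and 1 and 0 higher of 24 oxidative phosphorylation genes. Of 13 astrocyte markers 2 rose and 2 fell (3 and 3 adjusted over the list alone), against 0 and 5 after scaling. Of 10 oligodendrocyte precursor markers 1 rose and 2 fell (2 and 3 adjusted over the list alone), 4 of 8 blood cell and meningeal markers rose (4 adjusted over the list alone) and 1 of 4 lymphocyte markers fell (1 adjusted over the list alone).

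limma called 2747 genes higher and 588 lower of 13880 tested at 24 h, 714 and 50 of them by at least 1 on the log2 scale. The groups did not overlap for 47.9% of the genes, where chance gives 10%. The median of all genes was 0.127 above sham, and scaling the libraries to equal median ratios moved it to 0.0013 and the calls to 1605 higher and 1027 lower, so 82.4% of the calls were higher in the values as deposited and 61.0% after scaling. Camera called 24 of 35 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.40 with an estimated correlation), and fry called 23. In the other comparisons of this report fry called 2 lists for 28 d against 24 h in the control arm and 0 elsewhere. The count of genes was 320 without R24h_C1, 2012 without R24h_C3, and 761, 563 or 761 without Sham_C1, Sham_C2 or Sham_C3. Of the 48 passing genes named here 37 passed without each library in turn.

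**Figure D2:**
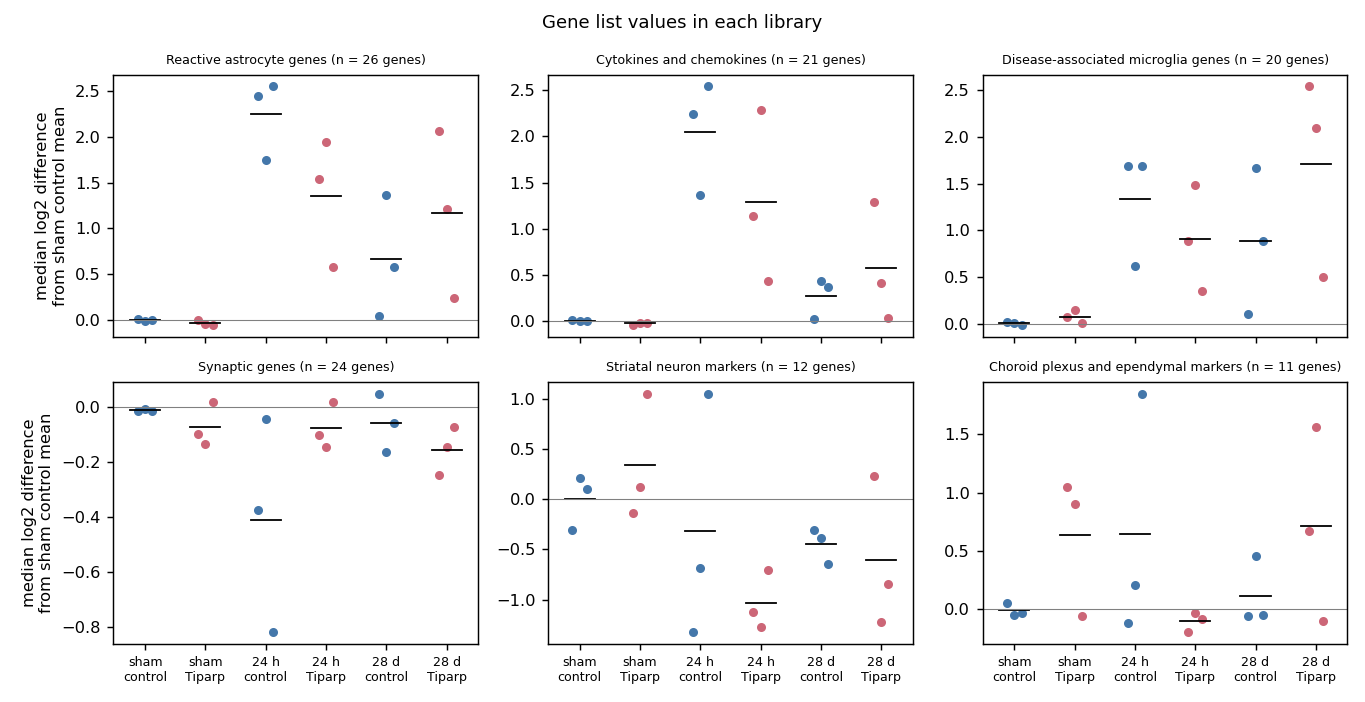
Median over the genes of a list of the log2(FPKM + 1) difference from the Sham_C mean (vertical axes) in each of the 18 libraries, by group (horizontal axes), for 6 of the 36 lists. Blue points are control-arm and red points Tiparp-arm libraries, and black lines are the means of 3 libraries, with the reactive astrocyte list between 1.75 and 2.55 in R24h_C and between 0.58 and 1.94 in R24h_T.

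Control-arm cortex at 28 d, set against 24 h, shows the later course. Most genes that differed were lower at 28 d. The R24h_C libraries are also those compared with sham above, so the calls here are not independent of that comparison. Spp1 fell from 528 ± 271 to 32.2 ± 26.3 FPKM (-4.34, SE 0.88, limma adjusted p = 0.0464). Hmox1 (-4.19), S100a9 (-4.32), Timp1 (-3.99), Ccl2 (-3.93), Cxcl1 (-3.77), Il11 (-3.76) and the peptidase inhibitor Ctla2a (-3.71) fell with it. Reactive astrocyte genes fell in 10 of 26 (22 adjusted over the list alone), cytokines and chemokines in 9 of 15 (15 adjusted over the list alone), heat shock genes in 8 of 14 (12 adjusted over the list alone), and endothelial markers in 6 of 12 (8 adjusted over the list alone). Of 19 disease-associated microglia genes 1 fell (2 adjusted over the list alone). Of 21 immediate early genes 6 rose and 4 fell (7 and 4 adjusted over the list alone), with Nr4a2 (1.98), Nr4a1 (1.74), Egr3 (1.56) and Egr4 (1.60) higher at 28 d. Synpo (1.95, adjusted p = 0.0152), Shank1 (1.15) and Shank3 (0.70) rose, the Shank genes being 2 of 24 synaptic genes and 2 adjusted over the list alone. Homeostatic microglia markers rose in 5 of 12 (6 adjusted over the list alone), with P2ry12 at 1.36 and Gpr34 at 1.34.

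limma called 169 genes higher and 671 lower of 13997 tested between 28 d and 24 h, 28 and 308 of them by at least 1 on the log2 scale, and 37.5% of the genes did not overlap between the groups (10% by chance). After median-ratio scaling 269 were higher and 432 lower, so the higher share was 38.4% in place of 20.1%. Camera called 19 of 34 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.61 with an estimated correlation). No gene passed without R24h_C1 and 2 passed without R24h_C3, 2913 without R24h_C2, and 45, 55 or 1 without R28d_C1, R28d_C2 or R28d_C3. Of the 17 passing genes named here 0 passed without each library in turn.

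At 28 d against sham in the control arm, which asks what remains late after ischemia, 7 genes passed. The Sham_C libraries are also those compared with Sham_T above, so the calls here are not independent of that comparison. The sodium channel Scn1a rose from 6.69 ± 0.111 to 12.4 ± 1.07 FPKM (0.79, SE 0.07, limma adjusted p = 0.0365) and Tmem88b from 5.47 ± 0.217 to 9.67 ± 0.441 FPKM (0.72, adjusted p = 0.0365). The stress kinase Mapk14 fell from 16.0 ± 0.415 to 8.15 ± 0.926 FPKM (-0.90, adjusted p = 0.0365) and the ubiquitin-conjugating enzyme Ube2o fell as well (-0.64, adjusted p = 0.0365). Tmem88b was also higher and Ube2o lower in Sham_T than in Sham_C. Like differences from Sham_C thus occurred for these genes without ischemia. The chemokine Cx3cl1 (-2.57) and the protocadherin Pcdhga4 (-1.53) fell and the neurosecretory protein Vgf (1.39) rose, and the values of these 3 genes formed a high and a low cluster over the 18 libraries, with both clusters within some other groups. No list member passed over all genes, but adjusted over the list alone 7 of 10 complement genes, 5 of 6 MHC and antigen presentation genes, 6 of 12 homeostatic microglia markers, 6 of 13 oligodendrocyte and myelin genes and 3 of 7 interferon response genes were higher. The complement component C1qa was at 69.1 ± 38.7 FPKM, against 21.3 ± 2.0 in sham (1.5, adjusted p = 0.338), and the receptor P2ry13 differed by 0.65 (adjusted p = 0.0828). Of 11 striatal neuron markers 4 were lower adjusted over the list alone (median -0.44).

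limma called 3 genes higher and 4 lower of 13419 tested at 28 d, with 1542 at an unadjusted p under 0.05 and 18.7% of the genes without overlap (10% by chance). Camera called 15 of 31 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.60 with an estimated correlation). The reactive astrocyte list was 0.04 above sham in R28d_C1, against 1.36 and 0.58 in R28d_C2 and R28d_C3, and 188 genes passed without R28d_C1, 3 without Sham_C1, 2 without Sham_C3 and 4 without R28d_C3. Of the 7 genes 2 passed without each library in turn.

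In the Tiparp arm, cortex at 24 h was set against Sham_T to see the early response with the shRNA present. The astrocyte filament Gfap rose from 39.0 ± 11 to 231 ± 71.6 FPKM (SD, n = 3 per group; 2.52, SE 0.29, limma adjusted p = 0.0331) and the chemokine Ccl12 from 0.307 ± 0.283 to 16.2 ± 11.8 FPKM (3.53, adjusted p = 0.0375). Gbp2 (2.47) and Gbp3 (1.70), the Fc receptor genes Fcgr4 (2.0) and Fcer1g (1.66), the leukocyte genes Cd52 (1.85) and Rac2 (1.45) and the MHC gene H2-D1 (1.45) rose. The blood cell and meningeal list had a median of 1.02, with 0 of 8 passing and 4 adjusted over the list alone, and was at 1.89 in R24h_T3 and at -1.5 in Sham_T3. Nr4a1 fell from 70.0 ± 5.10 to 16.9 ± 1.07 FPKM (-1.98, adjusted p = 0.00334), with Egr4 (-1.62) and Egr1 (-1.57), and Car12 (-1.10) and Dnajb5 (-0.92). The adenosine receptor Adora2a (-2.23), a striatal neuron marker, Lrrc10b (-1.87) and Syndig1l (-1.42) fell. Of 12 striatal markers 1 passed and 10 were lower adjusted over the list alone (median -1.34; adjusted p = 0.342 with an estimated correlation), and this list was 1.05 above the Sham_C mean in Sham_T3. The choroid plexus chloride channel Clic6 fell (-1.37), the 1 of 5 choroid plexus and ependymal markers to do so (2 adjusted over the list alone), where Ttr was at 624 and 501 FPKM in Sham_T1 and Sham_T2.

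Few members of the lists passed over all genes in the Tiparp arm at 24 h, and more did adjusted over the list alone. The counts were 1 and 17 of 18 reactive astrocyte genes (median 1.84), 2 and 12 of 13 interferon response genes, 0 and 10 of 11 complement genes, 1 and 6 of 8 MHC and antigen presentation genes and 1 and 6 of 6 cytokines and chemokines. Of 20 immediate early genes 3 fell, and 11 fell and 3 rose adjusted over the list alone. limma called 18 genes higher and 12 lower of 13509 tested, 1934 had an unadjusted p under 0.05, and 22.2% did not overlap between the groups (10% by chance). Camera called 20 of 34 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.34 with an estimated correlation). R24h_T3 lay closest to sham, with its reactive astrocyte list at 0.58 against 1.54 and 1.94 in R24h_T1 and R24h_T2. Without R24h_T3 825 genes passed, none without Sham_T3, and 11, 2, 1 and 4 without Sham_T1, Sham_T2, R24h_T1 and R24h_T2. Of the 18 passing genes named here 0 passed without each library in turn.

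Whether the 24 h response differed between the arms was tested as such. No gene passed the interaction in limma (14589 tested, lowest adjusted p = 0.415, 1593 at an unadjusted p under 0.05). The genes nearest to it included Synpo, whose response was 1.60 higher in the Tiparp arm (limma adjusted p = 0.415), the axonal protein Snph (1.14) and the synaptotagmin Syt7 (1.79), and, lower in the Tiparp arm, Cd24a (-1.99), the neurotrophic factor Manf (-0.93) and Isyna1 (-0.89). Tiparp itself was at -0.66 (limma adjusted p = 0.431). With a preset correlation camera called 12 of 35 lists for this interaction, and none with an estimated one. The reactive astrocyte list had a median difference of -0.81 (adjusted p = 0.866 with an estimated correlation), the monocyte and macrophage list -1.07, the synaptic list 0.45, the excitatory neuron list 0.69, the striatal list -1.13 and the choroid plexus and ependymal list -1.52, with 3 members of the last lower adjusted over the list alone and none of the other 5 lists. In R24h_C3 the striatal list was 1.05 above the Sham_C mean, against -1.32 and -0.68 in R24h_C1 and R24h_C2, and the choroid plexus and ependymal list 1.85, against -0.12 and 0.21. The neuronal lists were lowest in R24h_C3 as well. The excitatory neuron list was at -1.22 there, against -0.442 and -0.207 in R24h_C1 and R24h_C2. The synaptic list was at -0.819, against -0.374 and -0.0446. Over the 504 genes called at 24 h in both arms together with a change of at least 1 (474 higher, 30 lower), the median response was 1.75 in the control arm and 1.10 in the Tiparp arm. The median difference was -0.72, 94.4% of the genes had the smaller response in the Tiparp arm, and the exact two-sided permutation p was 0.21 over 400 labellings. Without R24h_T3 the difference was -0.37, and without R24h_C2 -0.98. Log2 differences of the arms correlated across 13307 genes (Pearson's r = 0.646, Spearman's rho = 0.513; genes are not independent replicates). Of 18 genes higher in the Tiparp arm 16 were also higher in the control arm (3.31 if independent), and of 11 lower 5 were also lower (0.477 if independent). Without R24h_C2 23 genes passed the interaction, 2 without R24h_T1 and 1 without Sham_T1.

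The arms were also set against each other directly at 24 h. limma called no gene of 14018 tested (lowest adjusted p = 0.421, 1012 at an unadjusted p under 0.05), and 12.0% did not overlap (10% by chance). Smallest in p were March8, a ubiquitin ligase, at -1.31 and Fbxo41 at 1.74, a gene with the high and low clusters described above, and none of these passed. The transglutaminase Tgm1 was at 4.38 ± 2.92 FPKM in R24h_T and 29.0 ± 18.1 in R24h_C (-2.49, adjusted p = 0.668), and Il11 at -2.71. The reactive astrocyte list had a median of -0.79, the monocyte and macrophage list -1.01 and the synaptic list 0.42, with no member passing adjusted over the list alone, and the choroid plexus and ependymal list -1.05, with 2 of 4 lower. The higher value of that list in R24h_C lay in R24h_C3, the library with Ttr at 1682 FPKM. In R24h_C3 the synaptic list was also lowest, at -0.819 from the Sham_C mean, against -0.374 and -0.0446 in R24h_C1 and R24h_C2. Camera called 12 of 34 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.74 with an estimated correlation). Without R24h_C1, R24h_C2 or R24h_T1 the count was 1, 2 or 1.

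At 28 d the Tiparp arm was set against its sham for the late response. limma called 1 gene higher and 1 lower of 13544 tested, with 1428 at an unadjusted p under 0.05 and 16.3% without overlap (10% by chance). Srgap3, a GTPase-activating protein of neurite growth, rose from 8.64 ± 1.02 to 35.2 ± 0.124 FPKM (1.91, SE 0.09, adjusted p = 0.00359), with a high and a low cluster of values that both occurred within 4 other groups. The gene that fell (-2.24, adjusted p = 0.0455) was a further entry with the symbol Map2k7 (ENSMUSG00000109061), named because so few passed. It is uncertain, since it shares its symbol with the main Map2k7 entry, which differed by 0.67 (adjusted p = 0.195). Adjusted over the list alone, 10 of 18 disease-associated microglia genes, 10 of 12 reactive astrocyte genes, 9 of 10 complement genes and 8 of 8 MHC and antigen presentation genes were higher, with the phagocyte protease inhibitor Cst7 at 4.05 (adjusted p = 0.234) and Gfap at 3.20 (adjusted p = 0.367). Camera called 20 of 33 lists with a preset correlation and none with an estimated one (lowest adjusted p = 0.36 with an estimated correlation). The median of the disease-associated microglia list was 2.54 above the Sham_C mean in R28d_T1, 2.09 in R28d_T2 and 0.51 in R28d_T3, and 568 genes passed without R28d_T3, 4 without Sham_T1, 1 without Sham_T2 and 0 without Sham_T3 or R28d_T2.

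limma called 1 gene for a difference between the late responses of the arms, and 42 of 100 splits of the same libraries called as many. Ube2o had a response 1.15 higher in the Tiparp arm (SE 0.09, adjusted p = 0.00165, 690 of 14242 genes at an unadjusted p under 0.05). The disease-associated microglia list had a median difference of 0.66 and the reactive astrocyte list 0.67, with no member passing adjusted over the list alone. Both had a camera adjusted p = 0.882 with an estimated correlation. With a preset correlation camera called 6 of 33 lists for this interaction, and none with an estimated one. No gene passed at 28 d over both arms with a change of at least 1, so the size of the late response could not be compared as at 24 h; 1 gene was higher and 2399 of 14242 had an unadjusted p under 0.05. Across 13189 genes the differences from sham of the arms had Pearson's r = 0.46 and Spearman's rho = 0.324; the calls were too few for a count of shared ones. The count for the interaction was 2 without R28d_C1 or R28d_T2 and 3 without R28d_C3 or R28d_T1, and 0 without Sham_T1, Sham_T2 and R28d_T2 together, the libraries with Ttr above 400 FPKM. That fit keeps 1 Sham_T library, and Ube2o was at 1.15 in it (adjusted p = 0.0875).

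At 28 d, with the arms compared directly, limma called no gene of 13779 (lowest adjusted p = 0.994, 347 at an unadjusted p under 0.05), and 6.09% did not overlap (10% by chance). The disease-associated microglia list had a median of 0.85, the MHC list 0.84, the complement list 0.66 the reactive astrocyte list 0.73, the choroid plexus and ependymal list 0.83 and the blood cell and meningeal list 0.55, with no member passing adjusted over the list alone and a lowest adjusted p = 0.66 with an estimated correlation. The disease-associated microglia list was at 2.54 and 2.09 in R28d_T1 and R28d_T2, where the choroid plexus and ependymal list was at 0.67 and 1.56. In R28d_T3 it was at 0.51, below R28d_C2 and R28d_C3 (1.67 and 0.88). With a preset correlation camera called 16 of 32 lists between the arms at 28 d, although no gene passed. Over all 3 conditions, with condition as a covariate, limma called no gene of 14984 (392 at an unadjusted p under 0.05). Tiparp was at -0.18 there, the receptor Gpr34 at 0.48 and Mfsd2a at -0.46, none of which passed (adjusted p = 1 for each). Of 4 cell cycle genes, a list with too few members in the other fits, 0 passed, also adjusted over the list alone (median 0.06).

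**Figure D3:**
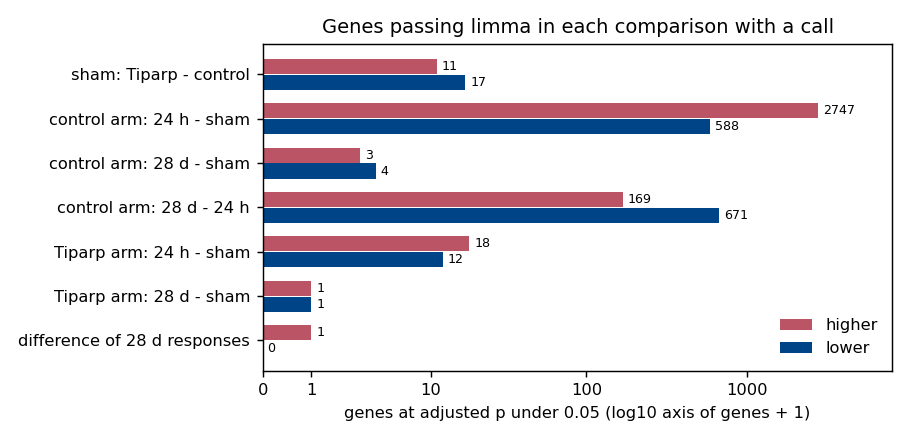
Number of genes that passed limma at an adjusted p under 0.05 (horizontal axis, log10 scale of the number plus 1) in each comparison with at least 1 such gene (vertical axis). Red bars count genes that were higher and blue bars genes that were lower in the group named first, from 2747 and 588 in the control arm at 24 h to 1 and 0 for the difference of the 28 d responses.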

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

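The gene below was singled out by a test planned before the data were examined, and its sham difference was looked at after the result was seen. The ubiquitin-conjugating enzyme Ube2o had a 28 d response that differed between the arms, by 1.15 on the log2 scale (limma, SE 0.09, adjusted p = 0.00165). It was at 28.9 ± 0.952 FPKM in Sham_C, 17.7 ± 0.634 in Sham_T, 18.2 ± 0.633 in R28d_C and 25.5 ± 1.86 in R28d_T (SD, n = 3), so a lower level in Sham_T than in Sham_C enters the difference. Without the libraries with Ttr above 400 FPKM, Sham_T1, Sham_T2 and R28d_T2, the Ube2o difference was again 1.15 and did not pass (adjusted p = 0.0875). That fit has 1 Sham_T library, assumed to vary like the others, so it does not tie Ube2o to choroid plexus RNA. As many genes passed the 28 d interaction in 42 of 100 splits of the same libraries, so chance cannot be excluded for Ube2o. limma called no gene between the arms directly at 28 d.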

How the results depend on the processing

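Leaving out genes with a high and a low cluster, and libraries with Ttr above 400 FPKM, were alternatives chosen after the result was seen; the others were planned, and edgeR and DESeq2 were not run, since they need counts. Of the alternatives for the named genes 1410 kept the direction and the side of the threshold, 455 lost and 17 gained a call, and for the lists 1201 kept, 193 lost and 34 gained it. The cause of the changes below was not tested. Without the Ttr libraries Sham_T keeps 1 library, assumed to vary like the others, so fewer libraries alone can end calls there. For the sham arms (28 genes) no filter gave 6, the replicate block 6, array weights 48 and all 18 libraries in 1 fit 0, and leaving out each library gave 5 to 52; Ttr libraries left out gave 21, with 4 of the 28 kept. For the arms at 24 h (0 genes) all 18 libraries gave 9 and leaving out each library 0 to 2. For the control arm at 24 h (3335 genes) no filter gave 1769, the block 1992, array weights 7561, libraries with Ttr above 400 FPKM left out 2012, and leaving out each library 320 to 4854. For the control arm at 28 d (7 genes) no filter gave 3, the block 1, array weights 12, all 18 libraries 0, clustered genes left out 4, and leaving out each library 2 to 188. For 28 d against 24 h (840 genes) no filter gave 4, the block 0, array weights 7146, all 18 libraries 2322, Ttr libraries left out 2, and leaving out each library 0 to 2913. For the Tiparp arm at 24 h (30 genes) a pseudocount of 0.1 gave 65, no filter 1, scaling 49, the block 70, array weights 79, all 18 libraries 63, clustered genes left out 55, Ttr libraries left out 0, and leaving out each library 0 to 825. For the Tiparp arm at 28 d (2 genes) a pseudocount of 0.1, no filter and scaling gave 1 each, the block 0, array weights 2407, all 18 libraries 0, clustered genes left out 0, Ttr libraries left out 0, and leaving out each library 0 to 568. For the 24 h interaction (0 genes) Ttr libraries left out gave 1 and leaving out each library 0 to 23, and for the 28 d interaction (1 gene) no filter gave 5, array weights 21, Ttr libraries left out 0 and leaving out each library 1 to 3. With each library left out the Tiparp difference was -0.0140 to 0.12 in sham and -0.0558 to 0.0705 at 28 d (0.0484 with array weights), and its 28 d interaction -0.126 to 0.009995 (0.0233 with array weights). List medians changed sign with a library left out, from -0.0105 to 0.0362 for the PARP family, -0.0342 to 0.00695 for the aryl hydrocarbon receptor pathway -0.111 to 0.0399 for astrocyte markers, -0.732 to 0.189 for blood cell and meningeal markers and -0.0355 to 0.581 for striatal markers in sham (the last 2 change sign without Sham_T3), and in the control arm at 24 h from -0.934 to 0.222 for striatal, -0.298 to 0.0214 for astrocyte and -0.00954 to 0.221 for inhibitory neuron markers and -0.0406 to 0.17 for growth-associated genes (-0.0406 with Ttr libraries left out). With scaling, list medians changed sign at 24 h in the control arm for inhibitory neuron markers (0.0541 to -0.0731) and growth-associated genes (0.0283 to -0.0695). They did so for 28 d against 24 h for inhibitory neuron markers (-0.0491 to 0.06) and oligodendrocyte and myelin genes (-0.00506 to 0.108). In the Tiparp arm at 24 h they did so for pan-neuronal (0.0183 to -0.0495) and inhibitory neuron markers (0.00749 to -0.051), growth-associated (0.00484 to -0.0355), aryl hydrocarbon receptor (0.0154 to -0.0429) and PARP family genes (0.0433 to -0.011). In the control arm at 24 h array weights gave -0.135 for growth-associated and -0.111 for oligodendrocyte and myelin genes, and no filter 0.0294 for lymphocyte markers. The smaller median response at 24 h in the Tiparp arm kept its direction and did not pass with a pseudocount of 0.1, no filter, scaling, clustered genes left out or each library left out (-0.37 to -0.98); the other alternatives were not run for it.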

Other observations

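The tests of Gene Ontology terms, value clusters, overlapping gene models, glucocorticoid and clock genes and spread were chosen after the result was seen. The response size and the splits were planned, but what they would decide was written after their values were seen. Gene Ontology terms, tested among genes higher at 24 h in the control arm, included the proteasome complex (47 of 62 genes, 12.8 by chance, adjusted p = 3.71e-17), which degrades ubiquitin-tagged proteins, angiogenesis (78 of 163, 33.6 by chance) and cell redox homeostasis (32 of 56, 11.5 by chance). Of 2654 terms 251 passed. Among lower genes 15 passed, including the postsynaptic density (32 of 196, 7.33 by chance, adjusted p = 4.01e-09), and potassium ion transmembrane transport (12 of 93, 3.48 by chance). Between 28 d and 24 h 132 of 2663 terms passed among lower genes, including the proteasome complex (18 of 62, 3.1 by chance), and 3 among higher genes. Both comparisons use the R24h_C libraries, so the proteasome complex in the second is not a separate finding. The 840 calls behind it fell to 0 without R24h_C1 and 2 without R24h_C3. These term tests treat genes as independent, so their p-values do not measure the spread between libraries. They used the values as deposited and were not run after scaling.

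Slc2a3, Chd3os, Fbxo41 and Fam109a between the sham arms, Cx3cl1, Vgf and Pcdhga4 in the control arm at 28 d and Srgap3 in the Tiparp arm at 28 d were bimodal, with values in a high and a low cluster. Over all genes 257 of 14984 had such clusters, found without the group labels with a gap of at least 0.5 log2 and 3 SD, a limit kept after 4 and 5 SD were tried as well. They made up 4 of 28 genes called between the sham arms (14.3% against 1.42% of genes tested, Fisher's exact p = 0.000611), 3 of 7 in the control arm at 28 d (42.9%) and 1 of 2 in the Tiparp arm at 28 d. There was no such excess in the control arm at 24 h (1.47% against 1.47%, Fisher's exact p = 1). In the Tiparp arm at 24 h 0 of 30 had clusters, and so few calls cannot show whether there was an excess. For 28 d against 24 h the excess just missed the threshold (2.26% against 1.45%, Fisher's exact p = 0.0515). If the groups set the cluster, each group should hold 1 cluster, but for these 8 genes 78.1% of the groups outside the comparisons held both (25 of 32, against 24.4 with permuted libraries). This does not carry over to all 257 genes, whose groups lay in 1 cluster more often than with permuted labels (2.78 groups per gene against 2.53, one-sided permutation p = 0.027). Of the 257 genes 51 were high in the same 3 libraries, R24h_C1, R24h_C3 and R24h_T2, among them the stress response genes Atf4, Ddit3 and Trib3, named after their values were seen; none of the 8 called genes belongs to this set. Reads given to one or the other of overlapping gene models could produce such clusters, since of bimodal genes with an overlapping gene 9.09% (14 of 154) had a partner that went the opposite way, against 1.03% of such genes drawn at random (11 of 1066). Partners that went the same way made up 7.14% and 7.79%, a control added after the first share was seen. Opposite partners thus cover few of the genes and this stays undecided; no biological explanation was tested.

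Glucocorticoid-responsive genes, on a list written after the sham values of Fkbp5, Plin4, Sult1a1, Tsc22d3, Zbtb16, Htra1 and Map3k6 had been seen, were lower in Sham_T than in Sham_C in 21 of 21, with 4 called. The 15 members not seen before were all lower too, with 0 called and a median of -0.401, and varied together between libraries of the 4 ischemia groups after the reactive astrocyte list was taken out. Their mean correlation was 0.623, against 0.0146 for random genes of like level. The one-sided p from 1000 random gene lists was 0.001, the smallest that 1000 draws allow, and does not measure the spread between libraries. Earlier forms of the test over 22 members gave 0.594 and 0.642. A list of genes regulated together can exceed random genes, and no other list was put to this test. Members such as Mt1, Mt2 and Cdkn1a are also on the metallothionein and p53 lists. The correlation thus does not single out a corticosteroid state that varies between animals or tissue. It was measured outside the sham groups, so it does not show that such a state differed between them. At 24 h the glucocorticoid list was at 0.525, -0.643 and -0.946 from the Sham_C mean in R24h_T1, R24h_T2 and R24h_T3. It was at 0.0488, 0.188 and 0.453 in R24h_C1, R24h_C2 and R24h_C3, so the R24h_T libraries went both ways. A lasting effect of the shRNA was not decided, with 20 of 22 members lower at 24 h (list median -0.688, 0 called) and a median of -0.0681 at 28 d, against -0.527 in sham. Nor was the time of day (median absolute difference of clock genes 0.212, none called).

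Fewer genes passed at 24 h in the Tiparp arm (30) than in the control arm (3335). Over 504 response genes the spread within R24h_T was 1.24 times that within R24h_C (SD 0.662 and 0.533), and with each library left out it ran from 0.681 without R24h_T3 to 3.25 without R24h_C2, so a larger spread is not settled. The spread was first taken over genes called in the control arm (1.47), and a limit set after the values were seen was then dropped for the range over libraries left out; over all genes it was 1.19, as in sham (1.19). The alternative, a smaller response with the shRNA, had an exact permutation p of 0.21 and stays open. Without R24h_T3 825 genes passed, and that library was singled out after its values were seen.

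For comparisons of 3 against 3 libraries the 10 splits are too few to decide on chance. The real count and the highest of the other splits were 28 and 11 between the sham arms (1 of 10 splits as large), 0 and 46 for the arms at 24 h (10 of 10), 0 and 6 at 28 d (10 of 10), 3335 and 1 for the control arm at 24 h (1 of 10), 7 and 11 at 28 d (2 of 10), 840 and 3 for 28 d against 24 h (1 of 10), 30 and 5 for the Tiparp arm at 24 h (1 of 10) and 2 and 2 at 28 d (4 of 10). For the 24 h interaction 100 of 100 splits gave as many genes (0 real, 302 highest), for the 28 d interaction 42 of 100 (1 real, 10 highest) and across the times 100 of 100 (0 real, 1 highest), so chance cannot be excluded for the 28 d interaction. With a real count of 0 every split is as large, which decides nothing for the others. Why other splits gave as many as 46 and 302 genes was not tested.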
